A study of Mus musculus with 6 samples.

How the data were processed

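Polyadenylated RNA from 6 clonal lines of mouse induced pluripotent stem cells (iPSCs) was sequenced, 3 lines with a Cas9 knockout of Tet1 and 3 non-targeted lines. Per the labels' protocols, all clones came from the same male iPSC line, which had been cultured for 14 passages and was then transfected with Cas9 protein, a Tet1 guide RNA and a single-stranded donor oligonucleotide, followed by 12 h with an enhancer of homology-directed repair. The labels give this same text for the knockout and the non-targeted clones and do not say whether the latter met the Tet1 guide and stayed unedited or were treated otherwise. Colonies were picked, grown for 4 more passages and expanded on mouse embryonic fibroblast (MEF) feeders, from which the iPSCs were removed before RNA was extracted. The libraries were made with a stranded mRNA kit, and the labels place all 6 in the same sequencing batch.

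The authors deposited whole-number counts of reads per gene, in a single table of 48440 genes, with no normalization. Per the submitters' processing notes, the tools were HISAT2 2.1.0, featureCounts 1.5.3 and DESeq2 1.18.1 with the mm10 build. Per the file headers, the counting was done with featureCounts 1.6.2, a reverse-stranded setting and the GENCODE M15 annotation of GRCm38.p5, over whole gene bodies with introns included. The command in the header sets no option to count multi-mapping reads or reads that overlap several genes, so both were left out of the deposited counts. This has a measurable effect. All 5565 genes that lie within a longer gene on the same strand have a total of 0 over the 6 libraries, among them Sox2, which lies within Sox2ot on chromosome 3 (34650405 to 34652461). In the gene lists 18 genes are placed in this way and are not analysed here. Genes with near-identical copies lose reads to multi-mapping, so the levels of the Zscan4, Usp17l and Rhox families and of Gapdh, which has many processed copies, are uncertain.

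The deposited counts summed to between 11937909 and 16189554 per library. Genes were kept with edgeR's filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), which left 14664 of the 25600 genes with any count. Libraries were scaled with TMM factors, and CPM, the count of a gene scaled to a common library size, was computed from the deposited counts with those factors. The groups were compared with edgeR's quasi-likelihood test with group as the only term and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. The common biological coefficient of variation was 0.188. Log2 fold changes are knockout minus non-targeted, with the standard error (SE) taken from the fold change and the F statistic. DESeq2 with its own size factors and filtering, and limma voom, were run as alternatives. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

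Before the data were examined, 19 gene lists were fixed: naive pluripotency, formative and primed pluripotency, 2-cell-like state, germline, DNA methylation machinery, imprinted genes, trophoblast, primitive endoderm, primitive streak and mesendoderm, Nodal pathway, neuroectoderm, Hox clusters, fibroblast (feeder) markers, p53 targets, cholesterol synthesis, glycolysis and hypoxia, interferon response, chromatin complexes (Sin3a, OGT and Polycomb subunits) and Y-linked genes. The 18 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Chromosomes were tested in the same way. The genes named in the text were chosen by a rule fixed before the data were examined: Tet1, then 11 pluripotency, Tet, Dnmt and Lefty genes whatever their result. The rule also takes the 10 largest rises and 10 largest falls past the threshold with a mean of at least 1 CPM, no overlap between groups, no predicted gene model and no member of the 2-cell-like families. From each list it takes up to 3 called members, or the 2 with the smallest p where none was called. Y-linked genes serve only as a check of the label male. As edgeR called no gene, the part of the rule on the largest changes was applied to the DESeq2 calls, a choice made after seeing the data. Genes named outside the rule are marked as such or named for their position or in a stated test, and 1 gene that the rule takes is not reported here.

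To look for stretches of shifted genes, the log2 CPM of each gene with a mean above 4 was set against the mean of the non-targeted libraries (of the other 2 for a non-targeted library) and smoothed with a running median of 21 genes. Runs of at least 20 genes beyond 0.35 on the log2 scale were kept. The ends of the stretches on chromosome 6 were then fitted in each library by dividing its 370 scanned genes into 3 pieces with the smallest sum of absolute deviations from the piece medians. Both steps were added after seeing the data. In simulated data with the same means, totals and dispersions, 200 of 14664 genes were changed. The edgeR test recovered 62% of the 2-fold and 98% of the 4-fold changes (100 genes each) and called 19 unchanged genes. DESeq2 recovered 73% and 98% and called 40 unchanged genes. For both tests the unchanged genes were a larger share of the simulated calls than the adjusted p of 0.05 sets. The recovered shares do not give the power in the real data. There edgeR called 0 genes, and Tet1, with a log2 fold change of -1.84, had an edgeR adjusted p of 0.0703. The single simulated stretch was found with a median of -1.04, and its fitted ends lay within 2 genes of the true ones.

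Replicates were checked for duplicates with chi-square values of their counts. The mean per gene between libraries of the same group lay between 7.85 and 43.4, above sampling noise in every pair, so no library was counted as a repeat. Alternatives tried were other scaling factors, other filters, the replicate number as a block, other tests, leaving out each library in turn, leaving out the genes of shifted stretches, and gene lists with no filter on low counts.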

Results

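The series asked how the loss of Tet1, an enzyme that oxidises 5-methylcytosine, changes gene expression in mouse iPSCs made from wild-type embryonic fibroblasts. The 3 Tet1 knockout libraries came from clones 14, 30 and 33 (replicates 1 to 3) and the 3 non-targeted libraries from clones 49, 51 and 52 (replicates 1 to 3). Each library is labelled as a separate clone of the same parental line, so p-values measure the spread between clones of that line and take each clone as independent. Total counts were 13070992, 11937909 and 13672879 in knockout replicates 1 to 3 and 12564763, 16189554 and 14597831 in the non-targeted replicates. The Y-linked genes Zfy1 and Kdm5d were detected in all 6 libraries, at 3.92 ± 0.655 and 28.7 ± 3.43 CPM in the knockout and 6.57 ± 1.02 and 37.0 ± 4.25 CPM in the non-targeted clones (SD, n = 3), as the label male requires.

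Tet1 (chromosome 10, 62804570 to 62899118, GRCm38) had 365, 231 and 288 CPM in knockout replicates 1, 2 and 3, against 1158, 966 and 1034 CPM in the non-targeted clones. The log2 fold change was -1.84 ± 0.16 (SE), with reads still present in every knockout clone. The position of the edit is not given in the sources used here, so whether these reads come from edited transcripts was not analysed here. In edgeR's quasi-likelihood test it did not pass, with adjusted p = 0.0703, the smallest of any gene and shared with Tenm3 and Ifitm1, which are named after their values were seen. Tet1 fell by 1.84 in DESeq2 (adjusted p = 9.43e-20). Tet3, another 5-methylcytosine oxidase, rose in DESeq2, with 39.0 ± 17.0 against 17.1 ± 3.23 CPM (SD, n = 3; log2 fold change 1.19 ± 0.31 SE; DESeq2 adjusted p = 0.00661; edgeR adjusted p = 0.120). Dnmt3l, a cofactor of the de novo DNA methyltransferases, fell in DESeq2 (log2 fold change -0.50 ± 0.13; DESeq2 adjusted p = 0.0235; edgeR adjusted p = 0.116), and Lefty2, a Nodal antagonist, rose in DESeq2 (0.88 ± 0.26; DESeq2 adjusted p = 0.0252; edgeR adjusted p = 0.128).

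Several genes that define pluripotent cells did not pass either test. Pou5f1, the core pluripotency factor, stood at 684 ± 8.54 CPM in the knockout and 780 ± 59.6 CPM in the non-targeted clones (log2 fold change -0.19 ± 0.07). Nanog had 471, 284 and 112 CPM in knockout replicates 1 to 3 and 462 to 564 CPM in the non-targeted clones (-0.79 ± 0.43). Tet2 gave 250, 108 and 62.3 CPM against 220 to 279 CPM (-0.83 ± 0.44), so that for both genes knockout replicate 1 lay within the non-targeted range. The maintenance methyltransferase Dnmt1 had a log2 fold change of -0.31 ± 0.08 (DESeq2 adjusted p = 0.0534). The de novo methyltransferases Dnmt3a and Dnmt3b had 0.15 ± 0.22 and 0.27 ± 0.32, both negative when knockout replicate 3 was left out (-0.15 and -0.04), and Lefty1 had 1.55 ± 0.57. Sox2 was listed at 0 in every library because of how nested genes were counted.

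**Figure D1:**
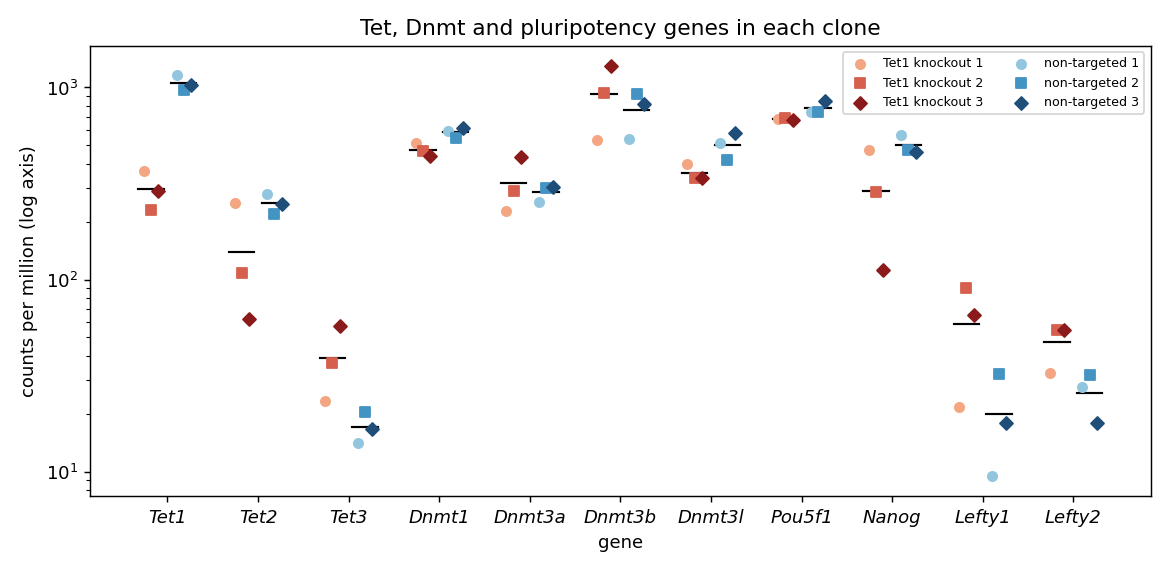
CPM (log axis) of Tet, Dnmt and pluripotency genes in each clone, with a point per library and a bar at each group's mean. Tet1 lies between 231 and 365 CPM in the knockout clones and between 966 and 1158 CPM in the non-targeted clones, and the knockout points spread widely for Tet2 and Nanog.

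Across all genes, DESeq2 called 1232 genes, of which 783 rose and 449 fell in the knockout, and 514 of them changed at least 2-fold (391 rose and 123 fell). The edgeR test, fixed as the main test, called 0 genes, with 3640 at an unadjusted p under 0.05, and limma voom called 1, Tet1. All 1220 DESeq2 calls tested in edgeR had an unadjusted p under 0.05 there, and 1115 of them had groups that did not overlap. Over all tested genes, 2171 lay higher and 2160 lower in every knockout clone than in every non-targeted clone, 29.5% of the genes, where the mean over the 10 splits of the libraries is 10% and the highest other split gave 21.004%. Knockout replicate 1 set the edgeR count: without it edgeR called 4404 genes (2287 up and 2117 down; 1785 at least 2-fold), and leaving out any other single library gave 0. The 2 knockout clones left in that comparison share stretches of lower genes on chromosome 6, and 332 of the 4404 calls lay inside shifted stretches. Of the 449 falls in DESeq2, 54 lay inside them, where 3.98% of the tested genes lie. The DESeq2 count moved to 4106 without knockout replicate 1, 306 without knockout replicate 2, 265 without knockout replicate 3, 183 without non-targeted replicate 1, 763 without non-targeted replicate 2 and 128 without non-targeted replicate 3. The first principal component held 66.8% of the variance and placed knockout replicates 1 to 3 at -13.2, 39.7 and 65.4 and the non-targeted replicates at -46.2, -13.2 and -32.5. In log2 CPM, knockout replicate 1 correlated at 0.984, 0.986 and 0.984 with the non-targeted replicates. Its correlations with knockout replicates 2 and 3 were lower, at 0.973 and 0.958. The split that gave 21.004% put knockout replicate 1 with non-targeted replicates 1 and 3.

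The largest falls in DESeq2 included Asz1 and Magea4, both members of the germline list, and 8 genes of no list. Scml2, a Polycomb-related germline protein, fell from 21.6 ± 11.1 to 3.87 ± 1.44 CPM (SD, n = 3; DESeq2 log2 fold change -2.49, adjusted p = 8.62e-07). Efhc2 fell from 12.8 ± 5.05 to 1.99 ± 0.544 CPM (-2.69, adjusted p = 1.74e-09) and Usp26, a deubiquitinase of the testis, from 15.4 ± 8.10 to 2.52 ± 1.96 CPM (-2.63, adjusted p = 0.000273). Asz1, a factor of the piRNA pathway, Magea4, Cox7b2, Ccdc172, Wbp2nl, Lrriq4 and Dnah17 fell with DESeq2 log2 fold changes of -3.31, -2.99, -2.72, -2.51, -2.12, -2.03 and -1.93, each from a mean of 2.27 to 4.99 CPM. Of these 10 genes, Scml2, Efhc2, Usp26 and Magea4 lie on the X chromosome. Asz1 lies at 18050964 to 18109061 on chromosome 6, within a stretch where genes were lower in knockout replicates 2 and 3, but was lower in all 3 knockout clones (0.690, 0.0827 and 0 CPM against 1.68 to 3.79 CPM).

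The largest rises in DESeq2 were of Postn, a secreted matrix protein of fibroblasts (DESeq2 log2 fold change 3.56), Prob1 (3.47), the giant cadherin Fat4 (2.97), the adhesion molecule Sdk1 (2.79), Ldb2 (2.75), the lipid transporter Mfsd2a (2.54), Fgfbp1 (2.45), the leukotriene receptor Cysltr1 (2.38), Vstm2b (2.37) and Cpz (2.31). Their knockout clones differed from each other: Prob1 had 1.07, 10.3 and 10.9 CPM and Fgfbp1 had 5.44, 25.9 and 26.7 CPM in replicates 1 to 3, against at most 0.811 and 4.80 CPM in the non-targeted clones. Postn reached 23.4 CPM in knockout replicate 3 and 2.15 and 2.56 CPM in replicates 1 and 2. All 20 of these genes had edgeR adjusted p between 0.103 and 0.148.

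Naive pluripotency genes were lower as a set. Of 28 tested members 26 had a negative log2 fold change (median -0.48), and camera gave adjusted p = 2.92e-06, but adjusted p = 0.359 with an estimated correlation. Adjusted over the list alone 0 members passed, as over all genes (6 had an unadjusted p under 0.05), and DESeq2 called 2. These were Stat3, which transduces the LIF signal (log2 fold change -0.56 ± 0.13; DESeq2 adjusted p = 0.0116), and Trim28, a corepressor of retrotransposons (-0.40 ± 0.11; DESeq2 adjusted p = 0.0405). The list median relative to the non-targeted mean was -0.06, -0.48 and -0.89 in knockout replicates 1 to 3, where that of the fibroblast list was 0.61, 0.79 and 1.97. In the non-targeted replicates the naive list median was 0.11, -0.14 and 0.06, so knockout replicate 1 lay within their range. In the formative and primed list, which did not pass camera (adjusted p = 0.0975), 0 of 24 members passed adjusted over the list alone and 0 over all genes (10 at an unadjusted p under 0.05; with no filter on low counts 7 rose and 3 fell adjusted over the list alone, against 0 over all genes), while Sox3 and Sall2 rose in DESeq2 (1.58 ± 0.43 and 1.67 ± 0.47; DESeq2 adjusted p = 0.00656 and 0.00423). That list passed without knockout replicate 1 (adjusted p = 0.0214) and without non-targeted replicate 2 (adjusted p = 0.0138).

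Genes of the 2-cell-like state, a transient totipotent-like programme, were higher in all 3 knockout clones, with list medians of 1.34, 1.69 and 1.36 relative to the non-targeted mean. Adjusted over the list alone 7 of 9 tested members rose, against 0 over all genes, and DESeq2 called 3. The filter on low counts had removed 21 of the 30 members with a count; without it 29 of 30 lay above 0, and 13 rose adjusted over the list alone, against 0 over all genes. With the filter, camera gave adjusted p = 1.57e-06, but adjusted p = 0.251 with an estimated correlation. Arg2, an arginase, rose from 0.407 ± 0.136 to 1.65 ± 0.466 CPM (log2 fold change 2.02 ± 0.41; DESeq2 adjusted p = 0.0234), and Usp17le from 0.385 ± 0.202 to 2.58 ± 1.77 CPM (2.68 ± 0.68; DESeq2 adjusted p = 0.0102). All levels in this list were low, and reads of its multi-copy members may be lost to near-identical copies.

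Germline genes were lower as a set, with a median log2 fold change of -0.45 and 36 of 43 tested members below 0 (camera adjusted p = 2.54e-06; adjusted p = 0.359 with an estimated correlation). Adjusted over the list alone 11 fell and 4 rose, against 0 over all genes, and in DESeq2 12 fell and 4 rose. Gtsf1, a piRNA pathway factor, fell in DESeq2 from 6.12 ± 0.946 to 2.05 ± 0.284 CPM (log2 fold change -1.57 ± 0.23; adjusted p = 0.000146), and the homeobox gene Rhox9 from 4.76 ± 1.04 to 1.41 ± 0.174 CPM (-1.75 ± 0.27; adjusted p = 0.000427). Both were lower in every knockout clone than in every non-targeted clone. The list median was -0.13, -0.35 and -1.16 in knockout replicates 1 to 3, beside fibroblast list medians of 0.61, 0.79 and 1.97. In the non-targeted replicates the germline list median was 0.20, -0.12 and -0.03, so knockout replicate 1 lay barely below non-targeted replicate 2.

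Primitive streak and primitive endoderm markers were higher as sets. In the primitive streak and mesendoderm list, 9 of 18 members rose adjusted over the list alone, against 0 over all genes, and 5 in DESeq2 (median log2 fold change 1.34; camera adjusted p = 1.62e-05; adjusted p = 0.359 with an estimated correlation). Eomes, a T-box factor of the streak, had 9.97, 23.2 and 15.1 CPM against 4.93 to 7.74 CPM (1.35 ± 0.33; DESeq2 adjusted p = 0.00381), and Pdgfra had a log2 fold change of 1.15 ± 0.28 (DESeq2 adjusted p = 0.0190). The list median was 0.28, 1.505 and 1.45 in knockout replicates 1 to 3 and -0.12, 0.26 and -0.22 in the non-targeted replicates. Knockout replicate 1 thus lay barely above non-targeted replicate 2. In the primitive endoderm list 13 of 22 members rose adjusted over the list alone, against 0 over all genes, and 9 in DESeq2 (median 0.96; camera adjusted p = 3.27e-06; adjusted p = 0.359 with an estimated correlation). The basement membrane collagen Col4a2 rose in DESeq2 from 23.4 ± 1.71 to 60.9 ± 20.2 CPM (1.38 ± 0.22; adjusted p = 5.85e-06) and the collagen prolyl hydroxylase P4ha2 from 7.59 ± 1.22 to 15.8 ± 3.43 CPM (1.06 ± 0.22; adjusted p = 0.00165). The fibroblast list, described next, was also higher in these clones, with medians of 0.61, 0.79 and 1.97 in knockout replicates 1 to 3. The primitive endoderm medians, 0.33, 0.75 and 1.16, were likewise highest in replicate 3, while the primitive streak median was slightly higher in replicate 2.

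Fibroblast markers, listed because the iPSCs were grown on MEF feeders, rose as a set with a median log2 fold change of 1.29, and 29 of 31 tested members were above 0. Adjusted over the list alone 21 rose, against 0 over all genes, and 16 in DESeq2 (camera adjusted p = 8.47e-11; adjusted p = 0.359 with an estimated correlation). The list median relative to the non-targeted mean was 0.61, 0.79 and 1.97 in knockout replicates 1 to 3, and -0.36, 0.24 and 0.12 in the non-targeted replicates, and the median log2 fold change without knockout replicate 3 was 0.73. Col6a2 rose in DESeq2 from 7.76 ± 1.21 to 18.8 ± 7.30 CPM (1.28 ± 0.28; adjusted p = 0.00215) and Fstl1 from 67.4 ± 1.83 to 93.2 ± 10.6 CPM (0.47 ± 0.10; adjusted p = 0.0142). In the interferon list, which did not pass camera (adjusted p = 0.0975), 4 of 24 members rose adjusted over the list alone, against 0 over all genes, and 4 in DESeq2. They included the class I histocompatibility genes H2-K1, from 13.7 ± 4.27 to 47.8 ± 15.1 CPM (1.80 ± 0.30; DESeq2 adjusted p = 1.30e-06), and H2-D1 (1.55 ± 0.34; DESeq2 adjusted p = 0.000958). The interferon list passed camera when knockout replicate 1 (adjusted p = 0.0127), non-targeted replicate 2 (adjusted p = 0.0382) or non-targeted replicate 3 (adjusted p = 0.0276) was left out.

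**Figure D2:**
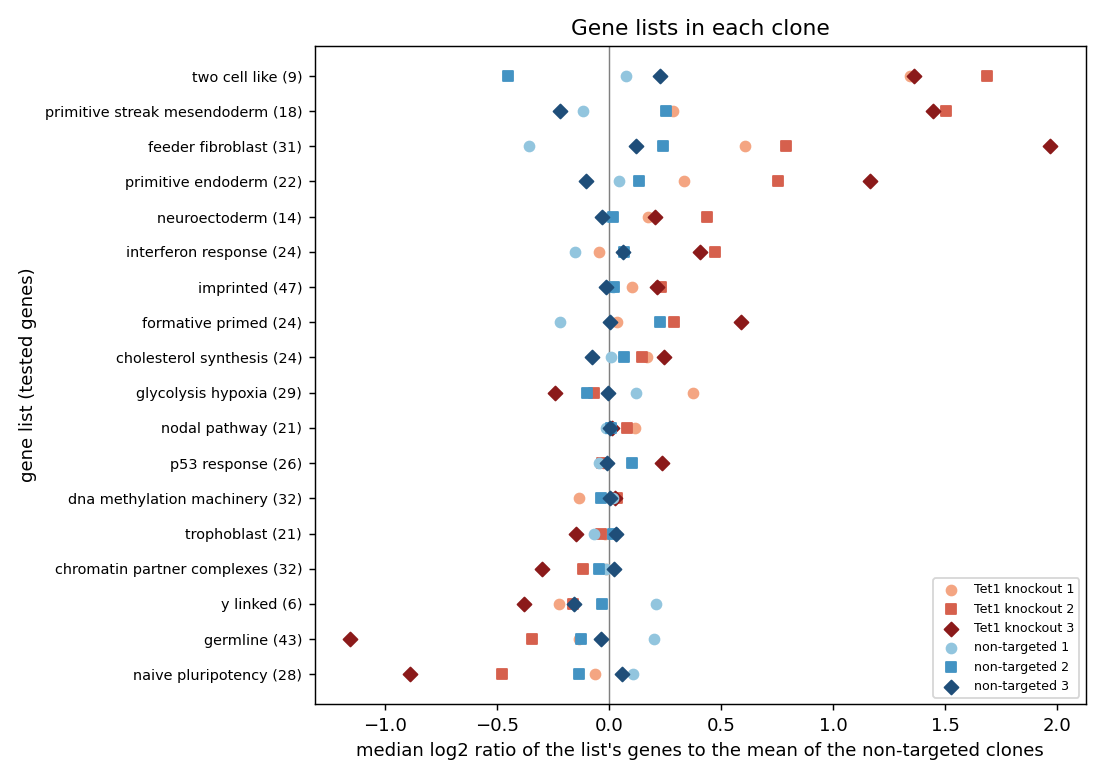
Median log2 ratio of each tested gene list to the mean of the non-targeted clones (horizontal axis), with a point per clone and the number of tested genes after each list's name. The 2-cell-like medians of the knockout clones lie together at 1.34, 1.69 and 1.36, while those of the naive pluripotency list spread from -0.06 to -0.89.

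Cholesterol synthesis genes were higher by small amounts, with 20 of 24 above 0 (median log2 fold change 0.20; camera adjusted p = 0.0132; adjusted p = 0.359 with an estimated correlation). Cyp51 and Sc5d, enzymes of the late pathway, rose adjusted over the list alone, against 0 over all genes, and in DESeq2 (0.54 ± 0.12 and 0.65 ± 0.15; DESeq2 adjusted p = 0.0112 and 0.0103). Chromatin complex genes were lower as a set, 22 of 32 below 0 (median -0.13; camera adjusted p = 0.0289; adjusted p = 0.359 with an estimated correlation). This call was lost without knockout replicate 3 (camera adjusted p = 0.100). The list medians of -0.01, -0.12 and -0.30 in knockout replicates 1 to 3 stood beside fibroblast list medians of 0.61, 0.79 and 1.97. In the non-targeted replicates the chromatin list median was -0.01, -0.04 and 0.02, so knockout replicate 1 lay within their range. Sin3a, the scaffold of a histone deacetylase complex that binds Tet1, was the only member to fall adjusted over the list alone, against 0 over all genes (-0.54 ± 0.11; DESeq2 adjusted p = 0.00356), and L3mbtl2 had -0.29 ± 0.08 (DESeq2 adjusted p = 0.0575). In DESeq2 1 member rose and 1 fell.

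The other lists did not pass camera. In the DNA methylation list (adjusted p = 0.174) 4 members fell, among them Tet1, Dnmt3l and Dnmt1, and Tet3 rose, adjusted over the list alone, against 0 over all genes. Among imprinted genes (adjusted p = 0.240) 3 rose, among them Gnas, and Dio3 fell adjusted over the list alone, against 0 over all genes, with log2 fold changes of 1.05 ± 0.24 for Gnas and -1.05 ± 0.22 for Dio3. In the Nodal pathway list (adjusted p = 0.206) 3 of 21 members rose adjusted over the list alone, against 0 over all genes, among them the feedback inhibitor Pmepa1 (0.59 ± 0.12) and the signal transducer Smad3 (1.15 ± 0.26), and in DESeq2 6 rose and 1 fell. In the neuroectoderm list (adjusted p = 0.240) Msi1 rose (0.77 ± 0.16) and Pax6 fell (-1.33 ± 0.28) adjusted over the list alone, and in the trophoblast list (adjusted p = 0.778) Cited1 rose (1.58 ± 0.33), each against 0 over all genes. In DESeq2 the trophoblast gene Wnt7b fell (-0.80 ± 0.22, adjusted p = 0.0199) and 2 trophoblast genes rose, Cited1 among them. No member of the p53 (adjusted p = 0.820), glycolysis and hypoxia (adjusted p = 0.421) or Y-linked list (adjusted p = 0.102) passed adjusted over the list alone or over all genes in edgeR, where 9, 7 and 2 members had an unadjusted p under 0.05. With no filter on low counts, 4 p53 targets rose and 2 fell, 6 glycolysis genes rose and 1 fell, and 2 Y-linked genes fell adjusted over the list alone, against 0 over all genes. In that setting 14 imprinted genes rose and 4 fell over the list alone, with 1 rise over all genes. For DNA methylation genes 3 rose and 9 fell, with 1 fall over all genes. The rises and falls were 8 and 3 for Nodal, 5 and 1 for neuroectoderm and 4 and 3 for trophoblast genes, against 0 over all genes. In DESeq2 2 p53 targets fell, Ckap2 (-0.41 ± 0.09) and Zfp365 (-0.52 ± 0.14), and 2 rose. In the glycolysis list 3 rose in DESeq2, among them Ldha (0.30 ± 0.07) and Ddit4 (0.53 ± 0.13), and 1 fell. The glycolysis list passed without knockout replicate 3 (adjusted p = 0.0163), and the Y-linked list passed without knockout replicate 2 (adjusted p = 0.0107) and without non-targeted replicate 3 (adjusted p = 0.000354). Only 4 Hox genes were tested, and of these Hoxc13 had a log2 fold change of -1.02 ± 0.34.

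Clonal iPSC lines can gain or lose chromosomes, so genes were also compared by position. Chromosome 6 was the only chromosome to pass camera, with a median log2 fold change of -0.19 over 743 genes (adjusted p = 0.000508; adjusted p = 0.988 with an estimated correlation). Its shift lay in knockout replicates 2 and 3. From 100833622 to 149563329 the median log2 ratio to the non-targeted mean was -1.001 in replicate 2 and -0.98 in replicate 3 over 152 genes, against -0.03 in knockout replicate 1 and between -0.03 and 0.02 in the non-targeted clones. From 3498382 to 42360213 the medians were -0.56 and -0.58 over 82 genes, against 0.05 in knockout replicate 1, and the 136 genes between lay at -0.02 and -0.04. Nanog, at 122707489 to 122714633, lies within the stretch towards the end. Knockout replicate 2 also had a stretch of 45 genes on chromosome 14 (59201209 to 70351425) with a median of -0.99, where replicate 3 had -0.21. Knockout replicate 3 had a stretch of 22 genes on chromosome 4 (143389659 to 147947314) at -0.60, where knockout replicate 2 had -0.50 and the non-targeted clones 0.23, -0.04 and -0.28. The count of chromosomes past the threshold was 2 without knockout replicate 2, non-targeted replicate 1 or non-targeted replicate 2.

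**Figure D3:**
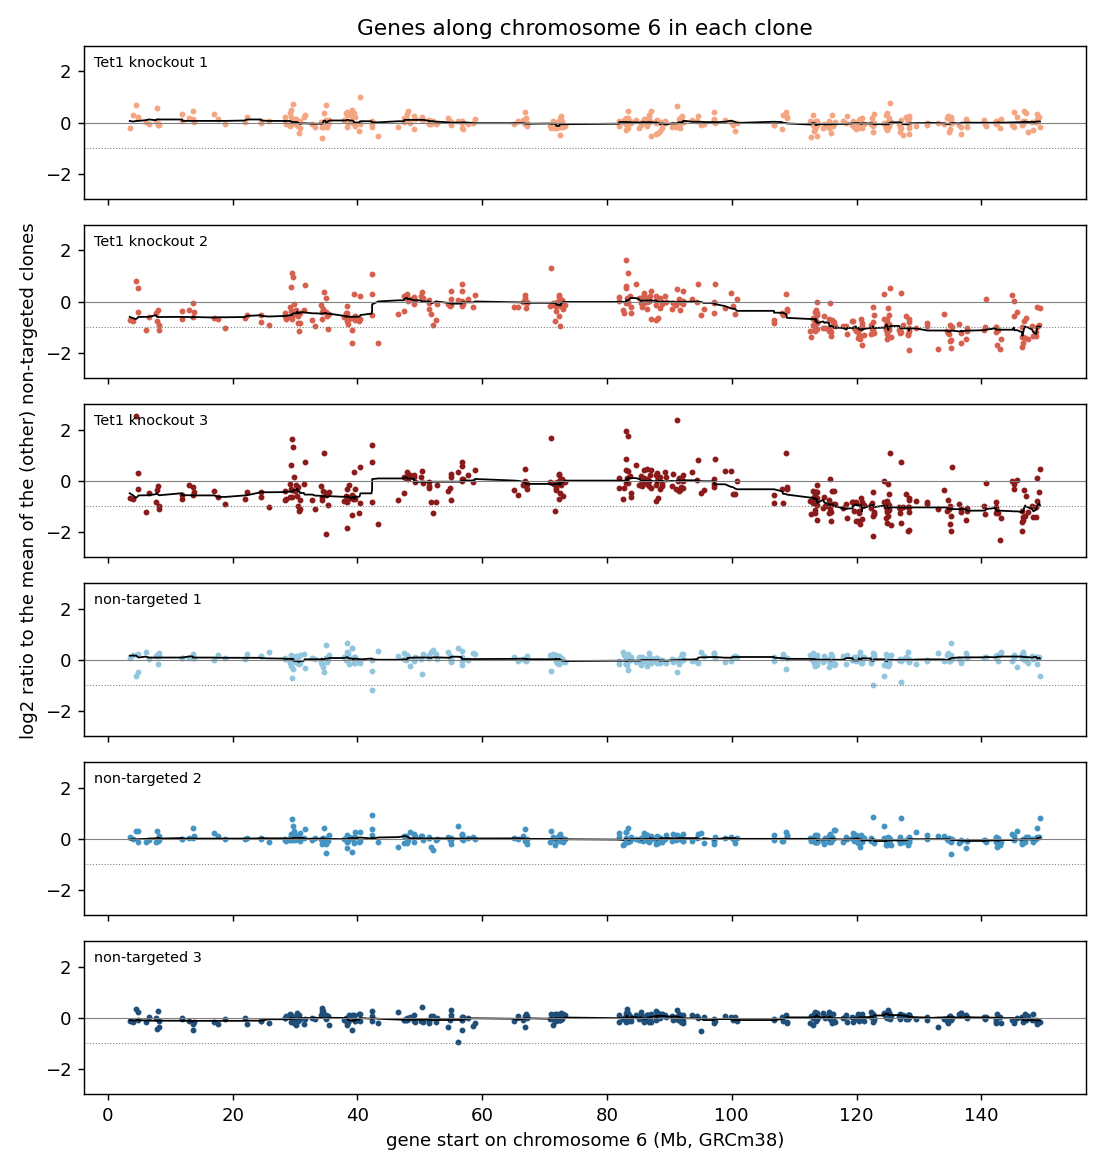
Log2 ratio of each scanned gene to the mean of the non-targeted clones along chromosome 6 (Mb), in a panel per clone, with the running median of 21 genes as a line and a dotted line at -1. In knockout replicates 2 and 3 the line lies near -0.56 and -0.58 at the start and near -1.001 and -0.98 towards the end, and it stays near 0 in the other clones.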

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

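Leaving out the genes of shifted stretches, DESeq2 with a library left out, and gene lists with no filter on low counts were chosen after seeing the data; the other alternatives were fixed beforehand. Against 0 genes in edgeR (0 at least 2-fold), the count was 0 with other scaling factors, with a floor of 1 CPM in 3 libraries, without the 15 mitochondrial genes (the only chromosome with a group median beyond 0.2) and at an adjusted p under 0.01, as was the 2-fold count with glmTreat. It was 159 (89 at least 2-fold) with no filter on low counts, 2 (both at least 2-fold, Tet1 and Tenm3) without genes in shifted stretches, 1 (at least 2-fold, Tet1) with limma voom, 1232 (514) with DESeq2 and 1277 (484) with DESeq2 without genes in shifted stretches. With a library left out it lay between 0 and 4404 (0 to 1785 at least 2-fold) in edgeR; in DESeq2 it was 4106 (1516), 306 (174) and 265 (106) without knockout replicate 1, 2 or 3 and 183 (100), 763 (487) and 128 (78) without non-targeted replicate 1, 2 or 3. Each replicate number is that of a separate clone. The deviations of same-numbered libraries from their group means correlated at 0.458, 0.109 and -0.0239, and knockout replicate 3 correlated best with non-targeted replicate 2 (0.459). Deviations within a group are tied to each other, so these correlations cannot show whether the numbers pair the samples. With the replicate block edgeR called 3 genes (3 at least 2-fold, Tet1, Tenm3 and Adgrl2, the latter pair named after their values were seen). The formative and interferon lists passed camera with that block (adjusted p = 0.00549 and 0.0463). The cause of these differences was not tested. Tet1 was lower under all 21 alternatives (log2 fold change -2.03 to -1.68) and passed in 13, with an adjusted p from 1.11e-56 to 0.371. Of the 66 named genes, 64 kept their direction in every alternative; Dnmt3a and Dnmt3b turned without knockout replicate 3 (edgeR -0.15 and -0.0445; DESeq2 -0.16 and -0.0545), and their highest edgeR values with a library left out were 0.34 and 0.54.

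Camera called 8 lists, 0 with an estimated correlation (adjusted p = 0.251 for the 2-cell-like list and 0.359 for the other 7), 2 with directional fry (2-cell-like and DNA methylation, the latter at 0.0390), 5 with mixed fry and 13 with no filter on low counts, where the formative and DNA methylation (0.0325 each), neuroectoderm (0.0385), interferon (0.00241) and Y-linked (0.00803) lists also passed; adjusted over each list alone, members that rose went from 69 to 133 and those that fell from 18 to 51. Directional fry gave adjusted p = 0.152 for the naive, 0.136 for the germline and primitive streak, 0.0827 for the primitive endoderm and cholesterol, and 0.150 for the fibroblast and chromatin lists. Mixed fry gave 0.119 for the naive, 0.0622 for the primitive streak and chromatin, 0.102 for the fibroblast and 0.0488 for the DNA methylation list. With a library left out, 47 of 48 values of the called lists stayed past the threshold in the same direction; the chromatin list ranged from 0.0127 to 0.100. Lists not called ranged from 0.0138 to 0.257 (formative), 0.0127 to 0.216 (interferon), 0.0163 to 0.902 (glycolysis), 0.000354 to 0.277 (Y-linked) and 0.353 to 0.966 (p53). The p53 list turned without knockout replicate 3 (0.396) or non-targeted replicate 1 (0.849), and the glycolysis list without knockout replicate 1 (0.0702). Chromosome calls numbered 1 to 2 with a library left out, and chromosome 6 passed each time.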

Other observations

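Some genes outside the naming rule, chosen after their values were seen, differed by about as much in each of the 3 knockout clones. Tenm3, a synaptic adhesion protein, rose in DESeq2 from 33.9 ± 3.94 to 80.1 ± 7.53 CPM (SD, n = 3; log2 fold change 1.24 ± 0.12 SE; DESeq2 adjusted p = 2.49e-13; edgeR adjusted p = 0.0703). Ifitm1, an interferon-induced membrane protein, fell in DESeq2 from 30.1 ± 2.17 to 12.0 ± 1.22 CPM (-1.33 ± 0.13; DESeq2 adjusted p = 2.98e-12; edgeR adjusted p = 0.0703). Gli1, a transcription factor of Hedgehog signalling, fell in DESeq2 from 36.9 ± 3.36 to 16.3 ± 1.69 CPM (-1.17 ± 0.13; DESeq2 adjusted p = 1.17e-09; edgeR adjusted p = 0.0830). Tmem40, which lies in the end stretch of chromosome 6 that was lower in knockout replicates 2 and 3, had 8.28, 6.95 and 5.03 CPM in knockout replicates 1 to 3 and 21.1 to 22.1 CPM in the non-targeted clones (DESeq2 adjusted p = 3.34e-11).

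Clones also differed within the groups in genes chosen after their values were seen. Knockout replicates 1 to 3 had 1.92, 48.9 and 22.9 CPM of T, the primitive streak marker brachyury, 3.07, 34.4 and 44.1 CPM of Fgf5, a marker of the post-implantation epiblast, and 622, 221 and 122 CPM of the naive factor Klf4. Non-targeted replicate 2 had 6.05 CPM of Meg3, 2.25 CPM of Rian and 0.25 CPM of Mirg, maternally expressed RNAs of the Dlk1-Dio3 imprinted region, where the other 5 clones had 113 to 281, 83.8 to 177 and 8.05 to 19.3 CPM. On chromosome 6, Copg2 had 56.8 and 47.9 CPM in knockout replicates 2 and 3 and 98.6 to 111 CPM in the other clones, and its neighbour Mest, a paternally expressed gene, had 164 and 133 CPM against 195 to 248 CPM. Peg10, another paternally expressed gene of that stretch, went the other way, with 1217 and 1054 CPM against 674 to 990 CPM.

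Of the tests that follow, those of edgeR splits, feeder cells left in the libraries and library size were fixed before the data were examined, and the others were chosen after the result was seen; those of whole chromosomes, dilution, loss of a copy and a common ancestor cell replaced earlier tests of the same explanations whose values had been seen. DESeq2 gave 1232 genes for the real grouping and at most 676 for any other of the 10 splits (1 of 10 gave as many), edgeR gave 0 and at most 0 with 3640 and at most 2702 genes at an unadjusted p under 0.05 (10 of 10 gave as many), and 10 splits are too few for a share under 0.05. Thinning to the smallest total kept 86.6% of the DESeq2 calls, which argued only weakly against a difference in library size. Totals spanned 11937909 to 16189554, so thinning had little to remove. Gain or loss of whole chromosomes was argued against as a direct source of most calls. Of the calls, 6.66% lay on chromosome 6, which holds 743 of the 14664 tested genes. It was the only chromosome other than Y and the mitochondrial one with a median beyond 0.2 in any library (the others reached 0.0806). Effects of such changes on genes of other chromosomes were not tested. Feeder cells left in the libraries, despite the removal step in the protocol, are a candidate explanation for the fibroblast genes among the rises: the list median was 1.29 and Col1a1, Col1a2 and Col3a1, collagens that this test named beforehand, had log2 fold changes of 1.39, 1.58 and 1.47 (0.73, and 0.59, 0.73 and 0.74, without knockout replicate 3), although 1 of the 31 list genes is in another list and all 31 also had counts in the non-targeted clones, which were grown on feeders too, so that these counts do not show the source and expression by the iPSCs stays open. Dilution by feeder cells was argued against for 15 of the 449 called falls. These passed below the lower 2-SE bound (-0.40) of Pou5f1, a gene fibroblasts lack, in a one-sided test adjusted over all genes. For the rest of the called falls dilution stays open, as 3.34% is a share that low power would also give. For the naive list as a set, the values argue against dilution as the only source of its fall in knockout replicates 2 and 3. The list medians were -0.06, -0.48 and -0.89 in knockout replicates 1 to 3. Pou5f1 stayed at 684, 692 and 675 CPM in the same clones, and dilution would lower both alike. An effect of Tet1 loss stays open for both the rises and the falls.

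The stretch at the end of chromosome 6 in knockout replicates 2 and 3 may reflect loss of 1 of 2 copies, which stays open: the genes that defined the stretch had medians of -1.001 and -0.98, close to the -1 that such a loss gives, but 98 genes that the scan had left out for their low level had -0.72 and -0.65 (between -0.03 and 0.03 in the other clones). The Tet1 knockout itself also stays open, as the median of -0.033 in knockout replicate 1 (quartiles -0.14 and 0.07) is that of a single library. A common ancestor cell of the 2 clones that already carried the change is a candidate explanation for the sharing. The inner ends, fitted in each library separately but against the same non-targeted mean, lay 0 scanned genes apart. They fell between Casp2 (ending at 42282508) and Zyx (starting at 42349630) and between Edem1 (ending at 108859356) and Rad18 (starting at 112619850). Ends that differ within those gaps cannot be told apart, and noise in the shared mean could move both fits alike. The fit of the ends replaced running medians, which had left the explanation undecided. Running medians had put the start of the end stretch at 100833622 in replicate 2 and at 108107028 in replicate 3. If the clones do share an ancestor, the knockout group has fewer than 3 independent clones. That would affect every p-value and most of all the 4404 edgeR calls made without knockout replicate 1. The stretch at the start of the chromosome, with fitted medians of -0.57 and -0.59, falls short of the loss of 1 of 2 copies. Other changes of copy number in that stretch were not tested and stay open, and allele counts were not analysed here.

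The lower naive and higher primitive streak lists could in principle follow from lower dosage of list members inside the shifted stretches. Without genes in those stretches the medians were -0.48 and 1.33, which argues against that as the cause. Indirect effects of the stretches on genes elsewhere, a shared history of knockout replicates 2 and 3, and Tet1 loss itself stay open and were not tested. Knockout replicate 1, which had a Tet1 level of 365 CPM and no shifted stretch, had list medians of -0.06 and 0.28, against -0.48 and 1.505 in knockout replicate 2 and -0.89 and 1.45 in knockout replicate 3.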
